A study of Homo sapiens with 4 samples.

How the data were processed

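RDIP-seq, immunoprecipitation of RNA:DNA hybrids followed by strand-specific sequencing, was done on HEK293T and IMR-90 cells, with 1 immunoprecipitated and 1 input library per cell line (4 libraries, 1 per group). Per the labels' protocols, nucleic acid was sonicated, treated with RNase I, incubated with the S9.6 antibody and captured on magnetic beads. The library began at the synthesis of the second strand, in which dUTP marked the strand that replaced the RNA, and the marked strand was degraded before amplification. Per the submitters' processing notes, the tools were CASAVA 1.8, Bowtie 0.12.7, SAMtools 0.1.8 and MACS 1.4.2, and the genome build was hg19. Their settings, and the use of the input library in peak calling, were not given in the sources used here. Reads from repeated sequence, as near centromeres and chromosome ends, depend on how reads with several matches were treated, which was not given either. Amplified copies of 1 molecule cannot be told apart here, so intervals cover counting error only.

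Each cell line had 1 deposited peak list without a header, and the cell line of each was taken from the name the authors gave the list. The lists gave the position of each peak and 4 columns of values. The first 2 deposited columns of values held whole numbers, with 0.9 in place of 0, and were read as reads in opposite orientations. Their sum is called reads here. Which of them is the plus strand, and whether they follow the RNA or the DNA strand of the hybrid, was not stated, so the text speaks of the first and the second orientation. The deposited score in the next column is called skew, and it equalled the difference of those read numbers over their sum, with 0.9 for 0, within 1e-09 in all peaks of both lists. No listed peak had a skew near 0, so the lists hold only peaks that lean to 1 side, and the rule by which the authors chose them was not stated.

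The last deposited column held a fraction between 0 and 1 that the authors did not name. Its values were tested against a simple form, a mean over windows of 25 bp placed every 15 bp, each window giving the share of its bases that belong to some class. Multiplied by the number of windows and the window lengths, the fraction came out whole, within 0.0001, in 34945 of 34946 HEK293T and 57307 of 57308 IMR-90 peaks. With a peak length wrong by 1 bp it did so in at most 12.3% of peaks, with a step of 10 bp in at most 3.62%, and with a window of 20 bp in at most 13.6%. The fraction is therefore described as a base share, and the class of bases stayed open.

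The number of each peak in its list ran to 38994 in HEK293T and 63390 in IMR-90, so 4048 and 6082 numbers were absent from the lists analysed here, for a reason that was not stated. An unshared peak was said to have room for an unlisted partner where the numbering of the other list skipped at least 1 number between the peaks on either side of it. Random places had such room in 17.8% and 20.0% of cases.

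Lists were compared by an overlap of at least 1 bp, without regard to orientation. Expected overlap came from 1000 random placements of the IMR-90 peaks, each on its own chromosome with its length, leaving out stretches of over 1 Mb with no peak in either list (2853 of 3096 Mb remained). Alternative settings used 200 placements. Where peaks with room were counted as shared, the 1000 placements were combined with 100 placements of the unshared peaks. Regions were compared with 1000 placements of each list by peak midpoint, two-sided, and adjusted over 8 regions and 2 lists by the Benjamini-Hochberg method, with a threshold of 0.05. The orientation of overlapping pairs was tested with the exact binomial test, two-sided, and the correlation of reads by 100000 permutations. Shares have exact (Clopper-Pearson) 95% intervals. Positions are hg19, counted from 1. Chromosome lengths came from GenomeInfoDb 1.38.1 and Giemsa bands from circlize 0.4.16, and computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Chromosome Y was left out of values per chromosome and of named peaks. Peaks outside chromosomes 1 to 22 and X stayed in the list totals, the overlap and the orientation of pairs. On chromosomes 1 to 22 and X alone, the lists held 34804 HEK293T and 57128 IMR-90 peaks, with 23566 overlapping pairs. Of these peaks 66.2% and 40.9% were shared, and 99.8% of these pairs had the same orientation. Whether reads on chromosome Y came from sequence repeated on other chromosomes was not tested.

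The overlap test was tested on simulated data, with both lists placed at random on the genome. With 200 planted overlaps the test, here with 100 placements, passed in 10 of 10 simulations with a mean excess of 184 peaks. With none planted it passed in 0 of 10, but both lists had been placed in the way the test assumes. The simulation therefore checked the computation, and not how the test behaves on lists that cluster in the same regions. For a sample of HEK293T peaks, overlapping pairs equalled those from a direct comparison with all IMR-90 peaks, 209 of 209. The search for room found 5648 of 5648 simulated left-out peaks. The simulated list was numbered by position, so each left-out peak had to leave a number free. This checked the search only, and not whether room in the deposited lists means a left-out peak.

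Number, length and overlap of the peaks, orientation at shared peaks, read correlation and density per chromosome were planned before the data were examined. The base share, Giemsa bands, chromosome ends, centromeres, neighbouring peaks and reads on the minor side were taken up afterwards. Peaks to be named were fixed beforehand as those with the highest fold enrichment, score or p, or else the 10 longest of each list and the 10 overlapping pairs with the longest smaller peak. The lists held no fold or p, and the only score was the orientation skew, which does not rank enrichment, so the rule of length was used. Peaks and bands named for reads, base share, missing partners or ratio were chosen after their values were seen. The alternatives were other definitions of overlap, a circular shift of each chromosome, merging of peaks within 1 kb, chromosomes 1 to 22 and X, and, chosen after seeing the data, minimums of reads and skew, list lengths set by reads, and lists without chromosome ends and centromeres or without chromosome 19. The planned work on genes, annotation classes, gene lists and base composition from sequence was not run, because no genome or annotation on hg19 was used here. For the same reason no peak is assigned to a gene, exon or intron.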

Results

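RNA:DNA hybrids, in which an RNA strand is paired with its DNA template, were mapped by RDIP-seq in HEK293T and IMR-90 cells. HEK293T is a human embryonic kidney line that carries the SV40 T antigen, and IMR-90 is a line of human lung fibroblasts. Hybrids were captured with the S9.6 antibody after single-stranded RNA had been digested with RNase I, and the libraries kept the orientation of the RNA strand. The series holds 4 libraries, 1 immunoprecipitated and 1 input library for each cell line, and 1 peak list for each cell line was analysed. The HEK293T list held 34946 peaks with 1321178 reads, and the IMR-90 list held 57308 peaks with 1422782 reads. These sums cover reads inside peaks, and the total depth of each library was not given in the sources used here. No group was replicated, so each statement about HEK293T or IMR-90 describes 1 list, and no spread between replicates could be set beside a difference. Peaks are not replicates, and all confidence intervals are exact 95% binomial intervals that cover counting error only.

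The first comparison asked how large the mapped hybrid territory was in each cell line. IMR-90 had 1.64 times as many peaks as HEK293T, but its peaks covered only 1.38 times the length and held 1.08 times the reads. The HEK293T peaks covered 27.0 Mb, or 0.874% of the genome, and the IMR-90 peaks covered 37.4 Mb, or 1.21%. HEK293T peaks were longer, with a median of 663 bp (quartiles 540 and 870 bp) against 584 bp (quartiles 480 and 738 bp) in IMR-90. HEK293T also concentrated its reads in fewer places, since the 349 peaks with the most reads, 1% of its list, held 29.6% of them, whereas the top 573 peaks of IMR-90 held 15.1%. The median peak held 13 reads (quartiles 8 and 24) in HEK293T and 15 reads (quartiles 11 and 24) in IMR-90, so a typical peak rested on few reads in both lists. With 1 library per cell line these differences could not be separated from differences between libraries.

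The longest peaks lay mostly next to centromeres. Of the 10 longest peaks, 8 in HEK293T and 6 in IMR-90 were in or within 1 Mb of a centromeric band. All 10 of each list overlapped a peak of the other. Reads near centromeres can come from repeated sequence, and neither the treatment of reads with several matches nor the use of the input was given. Length and reads of these peaks, and their overlap, can therefore not be assigned to hybrids at these places alone. The longest HEK293T peak lay in 4p11 (hg19 chromosome 4, 49093060 to 49158695), spanned 65.6 kb and held 8902 reads. IMR-90 covered the same stretch of 4p11 with separate peaks of 30168, 21673 and 10952 bp, which held 1840, 1344 and 680 reads. The longest IMR-90 peak lay in 21p11.2, on the short arm of an acrocentric chromosome (chromosome 21, 10773493 to 10825958), spanned 52.5 kb and held 5192 reads. HEK293T divided that stretch into peaks that included 28.4 kb with 2968 reads and 20.2 kb with 2831 reads. In 10q11.21 the boundaries of the lists nearly coincided, from 42354936 to 42373957 in HEK293T and from 42354946 to 42373986 in IMR-90, with 2428 and 1091 reads. Away from centromeres, 1q42.13, the band that holds the 5S ribosomal RNA gene array, carried HEK293T peaks of 15.6 kb and 13.4 kb with 3772 and 2263 reads and an IMR-90 peak of 8.85 kb with 1513 reads (chromosome 1, 228757722 to 228766571). IMR-90 further had long peaks of 11.1 kb in 11p15.5, 8.45 kb in 8q21.2 and 7.60 kb in 1q12.

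The peaks with the most reads were picked after their values were seen, and most of them were short. After the peak in 4p11, HEK293T had its highest read numbers in 5q14.1 (8538 reads in 2.05 kb, chromosome 5, 79945841 to 79947890) and 11p15.4 (8172 reads in 2.26 kb, chromosome 11, 10529432 to 10531692). The shared peaks at these places held 1673 and 1891 reads in IMR-90. Whether these places are copies of sequence found elsewhere, such as in the mitochondrial genome, was not examined here, so their reads cannot be assigned to these places alone. IMR-90 had its highest read number in 5p15.33, in a peak that began at base 10001 of chromosome 5 and held 5550 reads, and HEK293T held 6584 reads there. The next IMR-90 peak lay in 1p22.2 (chromosome 1, 91852319 to 91853435) with 5495 reads. All 10 peaks with the most reads in each list overlapped a peak of the other list.

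The second comparison asked how far the hybrids of the cell lines coincided. Of the HEK293T peaks, 23148 (66.2%, interval 65.7 to 66.7%) overlapped an IMR-90 peak by at least 1 bp, and 23500 IMR-90 peaks (41.0%, interval 40.6 to 41.4%) overlapped a HEK293T peak. Random placement of the IMR-90 peaks on their own chromosomes gave 3.12% and 1.92%, so the observed overlap was 21.2 and 21.4 times as high (one-sided permutation test, p = 0.000999 in each direction, the smallest that 1000 placements can give). The excess depended on the setting, at 9.49 and 9.91 times with a gap of up to 1 kb allowed, 34.8 and 35.2 times in the 50% of each list with the most reads, and 42.1 and 42.7 times with the same orientation required. Peaks with many reads were shared most often. In HEK293T the shared part rose from 42.7% in the 25% of peaks with the fewest reads to 91.1% in the 25% with the most, and in IMR-90 it rose from 17.4% to 74.5%. Shared peaks had medians of 16 reads and 729 bp in HEK293T and 22 reads and 712 bp in IMR-90, against 9 reads and 572 bp and 13 reads and 523 bp for peaks found in only 1 list.

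**Figure D1:**
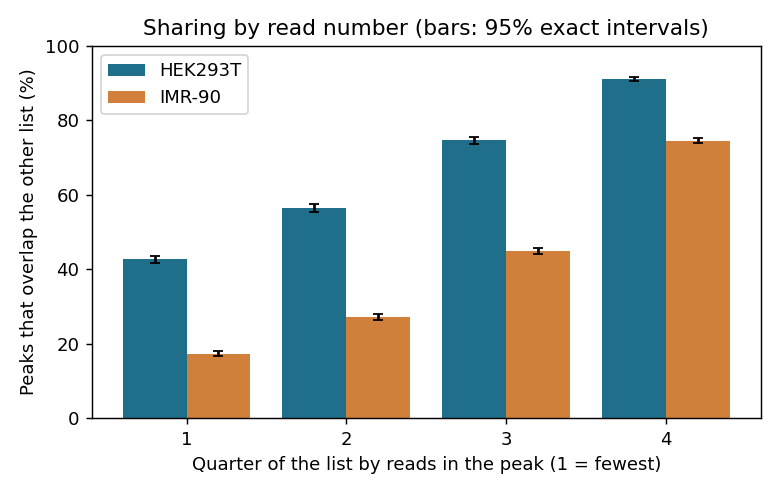
The bars give the percent of peaks that overlapped a peak of the other cell line, for each list divided into 4 equal groups by reads in the peak, with exact 95% intervals as error bars. The share rises in each step, from 42.7% to 91.1% in HEK293T and from 17.4% to 74.5% in IMR-90.

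Some peaks with many reads had no partner in the other list and no room for an unlisted one, and these too were picked by their read number after it was seen. In IMR-90 they lay in 11q14.1 (530 reads, chromosome 11, 85194652 to 85195292), 2p11.1 (443 reads, chromosome 2, 91736978 to 91740360), 6p12.2 (367 reads) and 7q21.13 (340 reads). In HEK293T they lay in 7q36.3 (216 reads, chromosome 7, 158459600 to 158461158), 13q12.11 (147 reads) and 1p36.32 (136 reads). Peak numbers absent from the lists, 10.4% of those in HEK293T and 9.59% of those in IMR-90, left room for a partner that was not listed at 29.6% of the unshared HEK293T peaks and 23.1% of the unshared IMR-90 peaks. The peaks named here were at places with no such room. Set aside for that reason were 20 unshared HEK293T peaks and 3 unshared IMR-90 peaks with more reads than those named, the highest in 1p36.33 (1641 reads) and 14q21.3 (1270 reads). Counting every unshared peak with room as shared would raise the shared part to 76.2% and 54.6%, but only 3.75 and 2.53 times the value from placement counted in the same way.

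At shared places the orientation of the reads was nearly always the same in both cell lines. Of 23683 overlapping pairs, 23625 (99.8%, interval 99.7 to 99.8%) had most of their reads in the same orientation, and 58 were opposite. The exact binomial test against equal chances gave a probability too small for the computer to hold. Equal chances are a weak standard here, because overlapping peaks share bases. The base share also went with the orientation in 98.1% of HEK293T and 99.2% of IMR-90 peaks. The part with the same orientation was still 99.6% (interval 99.4 to 99.7%) among pairs in which the smaller peak had fewer than 10 reads. Where both peaks held at least 50 reads, 2614 of 2616 pairs had the same orientation. The opposite pair with the most reads in its smaller peak, chosen for that reason, lay in 11q13.3, where a HEK293T peak of 512 reads (chromosome 11, 69964716 to 69966746) met the edge of an IMR-90 peak of 455 reads (69966745 to 69969153). The next by the smaller peak lay in 5q13.2, with 61 and 65 reads.

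Read numbers at shared places rose and fell together. Across the 23683 pairs, Spearman's rho was 0.606 and Pearson's r of the log2 read numbers was 0.69 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The 2 correlations run across peaks of 1 list each, and neighbouring peaks are not independent. HEK293T had more reads in 35.7% of the pairs, and its median was 17 reads against 22 reads in IMR-90. The median difference on the log2 scale was -0.32, HEK293T minus IMR-90, and was not corrected for library depth.

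The third comparison asked how the reads were oriented and how the orientation related to base composition. The orientations were close to equal in number, with 49.8% of HEK293T peaks (interval 49.3 to 50.3%) and 49.5% of IMR-90 peaks (interval 49.1 to 49.9%) in the first orientation. Within a peak the reads lay almost entirely on 1 side, and in 61.2% of HEK293T peaks and 35.7% of IMR-90 peaks no read had the other orientation. IMR-90 had more reads on the minor side, 6.22% of all reads in peaks against 2.08% in HEK293T. Among the 2616 shared pairs with at least 50 reads in both lists, the minor share was higher in IMR-90 in 2325 (88.9%, interval 87.6 to 90.1%), with medians of 4.48% and 0.588%. All listed peaks leaned to 1 side, the smallest skew on the first side being 0.508 in HEK293T and 0.459 in IMR-90, and on the second side -0.669 and -0.636. Peaks with a skew near 0 are not listed, so these values and those for the base share below hold for listed peaks only.

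The authors' base share of each peak, an average over 25 bp windows, separated the orientations almost completely in both cell lines. Its mean was 0.622 ± 0.0573 (SD over 17410 peaks) for peaks of the first orientation and 0.377 ± 0.0564 (17536 peaks) for those of the second in HEK293T. In IMR-90 the means were 0.630 ± 0.0518 (28388 peaks) and 0.370 ± 0.0523 (28920 peaks). The share lay above 0.5 for the first orientation or below it for the second in 98.1% of HEK293T peaks (interval 97.9 to 98.2%) and 99.2% of IMR-90 peaks (interval 99.1 to 99.2%). Which bases it counts was not stated in the sources used here. The exact binomial test against equal chances again gave a probability too small to hold.

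**Figure D2:**
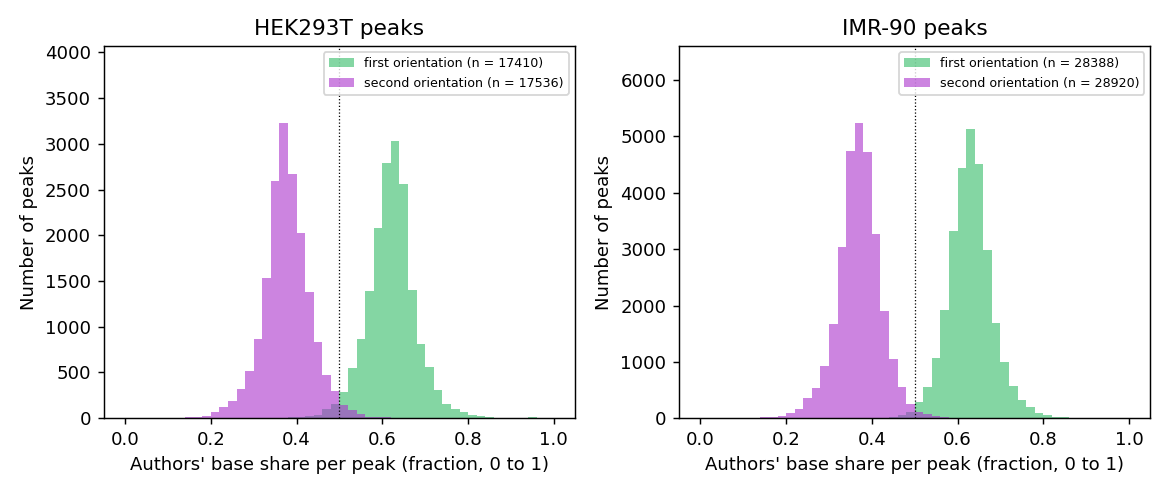
The histograms count peaks by the authors' base share (x axis, fraction from 0 to 1) for HEK293T (left) and IMR-90 (right), coloured by the orientation of most reads, with a dotted line at 0.5. The orientations form separate groups around 0.622 and 0.377 in HEK293T and 0.630 and 0.370 in IMR-90.

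Shared peaks had a more extreme base share than peaks found in only 1 list. With the share of second-orientation peaks replaced by 1 minus its value, so that both orientations are counted alike, the mean was 0.634 ± 0.0536 for shared and 0.601 ± 0.0566 for unshared HEK293T peaks, and 0.649 ± 0.0530 and 0.617 ± 0.0472 in IMR-90 (SD over peaks). The same measure rose with reads, from 0.604 to 0.649 in HEK293T and from 0.616 to 0.655 in IMR-90 between the 25% of peaks with the fewest and the most reads. Within each of the 4 groups by reads, shared peaks still lay higher, by 0.0189 to 0.0268 in HEK293T and by 0.0193 to 0.0299 in IMR-90. In 19p12 a peak of 5.26 kb with 1794 reads in HEK293T (chromosome 19, 23647551 to 23652814) had a base share of 0.104, and its IMR-90 partner of 5.14 kb with 1146 reads had 0.0946. In 4q35.2 the values were on the opposite side, 0.826 in HEK293T (4.25 kb, 1661 reads, chromosome 4, 189072085 to 189076335) and 0.846 in IMR-90 (784 reads). The lowest of the 5 IMR-90 values so chosen was 0.0799, in Xp22.33 (1723 reads, chromosome X, 487724 to 489706). The exceptions, 672 peaks in HEK293T and 487 in IMR-90, included places with many reads, such as 4q35.2 (2908 reads, base share 0.486 in the first orientation, chromosome 4, 190153847 to 190156779) and 5p15.2 (1704 reads, 0.518 in the second) in HEK293T. In IMR-90 they included the peak in 1p22.2 with 5495 reads (0.532 in the second orientation) and a peak in 13q33.3 with 1128 reads (0.503 in the second). All these peaks were chosen after their values were seen.

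The last comparison asked where on the chromosomes the hybrids lay. Both lists were densest on chromosome 19, a chromosome rich in genes, with 38.2 peaks per Mb in HEK293T and 41.5 in IMR-90. Chromosome 13 was the sparsest of 1 to 22 and X in both lists, with 5.83 and 12.5 peaks per Mb. These densities use the full length of each chromosome, and stretches without sequence or peaks were not taken out. Chromosomes with long stretches of that kind come out lower, so the order holds for full length only. The lists came closest in number on chromosome 19, where HEK293T had 0.921 times as many peaks as IMR-90, on chromosome 22 (0.889) and on chromosome 17 (0.880). They lay farthest apart on chromosome 18 (0.416), chromosome 4 (0.432) and chromosome 14 (0.435).

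**Figure D3:**
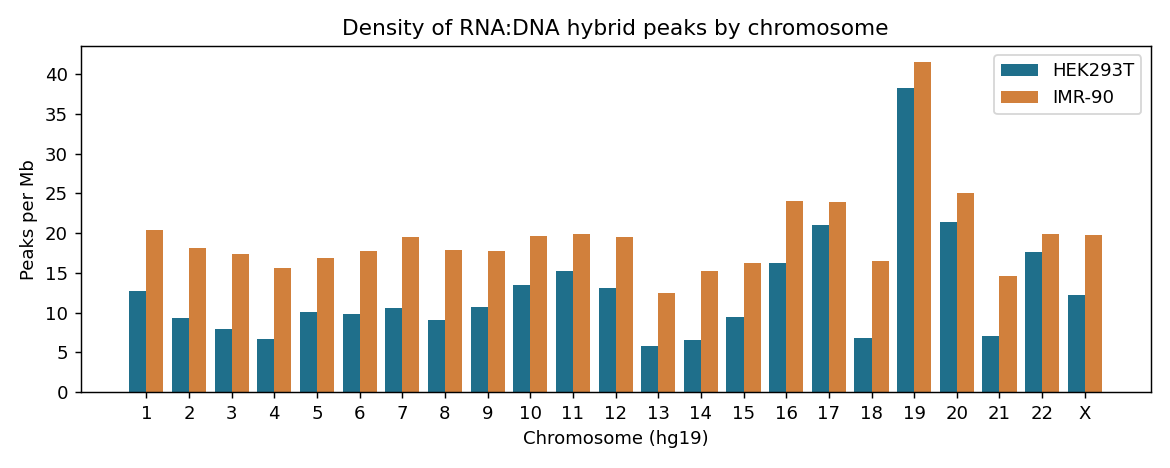
The bars give peaks per Mb of full chromosome length on chromosomes 1 to 22 and X (hg19) in each cell line. Chromosome 19 stands highest with 38.2 in HEK293T and 41.5 in IMR-90, and IMR-90 lies above HEK293T on every chromosome drawn.

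The densest band with at least 100 peaks in the 2 lists together was 19q13.33 in both, with 82.9 peaks per Mb in HEK293T and 75.3 in IMR-90. HEK293T, whose whole list held 0.610 times as many peaks as that of IMR-90, had more peaks in only 33 of 389 such bands. Its highest ratio was in 9q34.3, at the end of the long arm, with 209 peaks against 145 (ratio 1.44, interval 1.16 to 1.79), followed by 11q13.2 with 92 against 65 (1.42, interval 1.02 to 1.98), 11q13.1 with 125 against 94 (1.33, interval 1.01 to 1.76) and 16p13.3, at the end of a short arm, with 246 against 187 (1.32, interval 1.08 to 1.60). The lowest ratios were in 4p15.1 with 2.22 peaks per Mb against 12.5 (ratio 0.178, interval 0.102 to 0.296), 8p22 with 22 against 112 (0.196, interval 0.118 to 0.312) and 18q12.3 with 24 against 111 (0.216, interval 0.133 to 0.338). These bands were picked by the ratio itself, so the intervals of the most extreme ones are too narrow.

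Pale bands of the Giemsa stain, which are generally rich in genes, held more peaks than random placement gave, and the darkest bands held fewer. Giemsa-negative bands held 56.5% of HEK293T peaks (interval 56.0 to 57.0%) and 50.9% of IMR-90 peaks (interval 50.5 to 51.3%), 1.24 and 1.12 times the value from placement. The lightest of the positive classes gave 1.26 and 1.10 times, and the next class gave 1.02 in HEK293T, which did not pass the test (adjusted p = 0.266 by permutation), and 1.03 in IMR-90. The second darkest class gave 0.644 and 0.845 times, and the darkest gave 0.481 and 0.730. Bands of variable heterochromatin gave 0.445 and 0.594. The last Mb of the chromosomes held 1.77 times as many peaks as placed in HEK293T and 1.30 times in IMR-90, and 9.55% and 4.47% of the reads. Centromeric bands and the Mb on either side held 0.813 times the placed number in HEK293T. In IMR-90 they held 1265 peaks against 1260 placed, which did not pass the test (adjusted p = 0.889 by permutation). All other values in these regions had an adjusted p of 0.00228 in a two-sided permutation test with Benjamini-Hochberg adjustment over 8 regions in each of the 2 lists, the smallest these placements gave.

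The contrast between pale and dark bands was steeper in HEK293T. Peaks found in both lists occupy the same places, so only the unshared peaks can set the lists apart. Of the shared peaks, 55.9% in HEK293T and 56.0% in IMR-90 were in Giemsa-negative bands, and 1852 and 1870 peaks were in the darkest bands. Of the unshared peaks, the part in Giemsa-negative bands was 57.7% (interval 56.8 to 58.6%) in HEK293T and 47.4% (interval 46.9 to 47.9%) in IMR-90. The darkest bands held 6.33% (interval 5.90 to 6.79%) of the unshared HEK293T peaks and 14.8% (interval 14.4 to 15.2%) of the unshared IMR-90 peaks. The region results were chosen after the files had been looked at, and cell line and library cannot be separated in them.

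**Figure D4:**
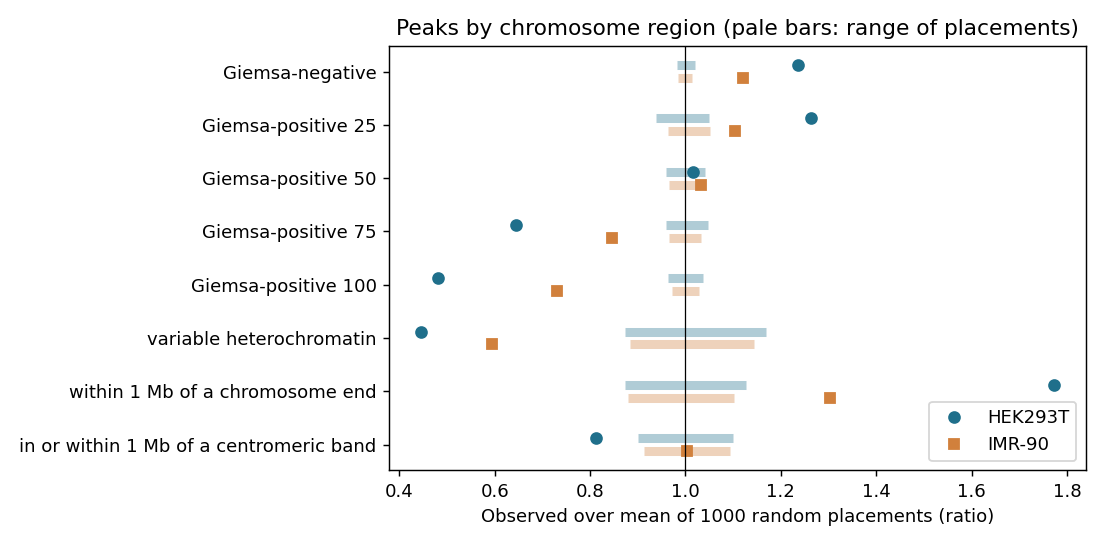
Each point is the number of peaks in a region divided by the mean of 1000 random placements (x axis, ratio), with circles for HEK293T, squares for IMR-90 and pale bars for the range of the placements. Giemsa-negative bands lie at 1.24 and 1.12, the darkest bands at 0.481 and 0.730, and chromosome ends at 1.77 and 1.30.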

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

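The test of the base share against a telomere repeat and all comparisons of Giemsa bands, ends and centromeres between the lists were chosen after the data had been seen. Each result here stood out because its share of peaks differed between the cell lines in Fisher's exact test over peaks, which compares these 2 lists and not replicated cultures. Many peaks stand in both lists and neighbours are not independent, so the test is too lenient and no p is given.

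HEK293T peaks lay in Giemsa-negative bands more often than IMR-90 peaks, by 5.57 percentage points. Lists of equal length by reads gave 5.82, so the IMR-90 peaks with the fewest reads do not account for it. That cut could hardly change the share, since the median in IMR-90 was 15 reads in these bands and 15 elsewhere. A longer list through depth or peak calling therefore stays open. Chromosome 19 does not account for the difference either, since it was 5.94 without that chromosome. HEK293T cells carry abnormal chromosome numbers, but compared within chromosome arms the difference was 5.51 and HEK293T was higher in 40 of 42 arms, which argues against copy number of whole arms. Differences between smaller copied segments, between libraries, or between the cell lines themselves stay open, since each line had 1 immunoprecipitated library, and the biological difference was not tested.

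The agreement between base share and orientation was lower in HEK293T than in IMR-90 by a small amount, the difference being -1.07 percentage points. The agreement itself is not chance imbalance of peaks with few reads, since it was 99.0% in HEK293T and 99.4% in IMR-90 in the 25% of peaks with the most reads. Whether the share counts purines on the reference strand was asked of peaks at telomeres. Peaks that began at base 10001 of a short arm, where the reference commonly starts with CCCTAA telomere repeats, had a median share of 0.355 (range 0.310 to 0.405, 9 peaks on 6 chromosomes), against 0.333 for purines in that repeat. All 9 were of the second orientation. Of that orientation, 52.3% of all HEK293T and 56.7% of all IMR-90 peaks lay as close to 0.333 as the test asked, so it could not decide for purines. The same repeat gives 0.167 for G or T, 0.5 for G or C, 0.667 for pyrimidines and 0.833 for A or C, all outside the range of the 9 peaks. These values argue against those classes as far as the peaks consist of the repeat, which was not examined. The class of bases stays open, and no biological explanation was tested.

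The remaining differences are HEK293T minus IMR-90 in percentage points. The lightest Giemsa-positive class differed by 2.46, the second darkest by -3.03 and the darkest by -4.56. The last Mb of the chromosomes differed by 0.998 and the surroundings of centromeric bands by -0.304.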

How the results depend on the processing

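The settings by reads, by skew and by region, the bound from absent peak numbers, all settings for the base share and Giemsa bands, and those for the read correlation other than reciprocal overlap were chosen after seeing the data. Of 99 alternative values for 13 results, 97 kept the direction and the side of the threshold or, for numbers and lengths, stayed within 1.5 times. This count says little on stability. Sharing and agreement lay so far above their thresholds that they could hardly change side. Some alternatives repeat the main value, as for base share and Giemsa bands in HEK293T with lists of equal length, which leave that list whole. A circular shift changes only the expected overlap. The exceptions were the number of HEK293T peaks, 22937 with at least 10 reads and 22836 with a skew of at least 0.8 on either side, against 34946, because both settings remove peaks. The shared part ran from 54.4% to 76.2% in HEK293T and from 34.3% to 54.9% in IMR-90. Lists of equal length gave 54.4% and 54.9%, which lie close together by construction, since nearly every overlap joins 1 peak of each list. The excess of sharing over placement, 21.2 and 21.4 times, moved more. It was 9.49 and 9.91 times with a gap of up to 1 kb, 42.1 and 42.7 with the same orientation required, 34.8 and 35.2 in the 50% of each list with the most reads, and 3.75 and 2.53 with absent numbers counted as shared. Agreement of orientation ran from 99.7% to 99.9%, Spearman's rho from 0.599 to 0.681 and the Giemsa-negative difference from 5.34 to 7.26 points. Placements for the settings of 50% reciprocal overlap and of midpoints counted any overlap of 1 bp, so their excess over chance is a lower bound. The planned settings by p, fold or score were not run, since the lists hold none that ranks enrichment, and neither were those for genes, annotation classes and sequence. The effect of depth was not tested. In the 25% of peaks with the fewest reads, HEK293T peaks held 3 to 8 reads and IMR-90 peaks 3 to 11. No paired analysis was possible because each group had 1 library.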

Other observations

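The tests of telomere ends and of neighbouring peaks were chosen after the data had been seen. Peaks at base 10001, the first sequenced base of several short arms, all had most of their reads in the second orientation. HEK293T had such peaks on chromosomes 1, 4, 5, 7 and 9 with 1641, 119, 6584, 430 and 8 reads. IMR-90 had them on chromosomes 4, 5, 7 and 18 with 144, 5550, 328 and 587 reads.

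The first and last sequenced base were taken to lie 10 kb inside each chromosome end, which was not checked against the sequence. Where the sequence begins or ends farther inside, the windows are shorter than stated or empty. Within 100 kb of these positions, the second orientation made up 83.3% of 48 peaks on short arms in HEK293T. On long arms it made up 40.6% of 32 peaks (Fisher's exact p = 0.000108). These peaks lay on 12 and 15 chromosomes, and neighbours are not independent, so Fisher's test over peaks is too lenient in this paragraph. In IMR-90 the values were 78.7% of 47 peaks and 64.9% of 37 peaks (Fisher's exact p = 0.218). The hypothesis was that reads run toward the chromosome end on both arms. Which strand the second orientation follows was not stated, so a difference between arms cannot tell reads running toward the end from reads running away. The hypothesis was left open. Within 1 Mb the second orientation was found in 268 of 485 and 285 of 559 peaks in HEK293T (Fisher's exact p = 0.172) and 301 of 537 and 349 of 611 in IMR-90 (Fisher's exact p = 0.721).

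Neighbouring peaks had the same orientation in 81.2% of HEK293T and 79.3% of IMR-90 cases at gaps under 1 kb, in 59.8% and 60.8% at 1 to 5 kb, and in 51.9% and 52.0% at 5 to 100 kb. One region divided into several peaks could account for the closest neighbours, but at 5 to 100 kb both values lay above the highest of 1000 shuffles, although at 5 to 20 kb alone the HEK293T value of 51.6% lay below the highest shuffle, 51.9%. Whether shared base composition accounts for it could not be decided, since the base share lies on the side of the orientation in 98.1% and 99.2% of peaks and the value it predicts nearly restates the observed one. The observed value exceeded it by at most 1.45 standard errors at 5 to 100 kb. In IMR-90 the excess was 2.42 at 5 to 20 kb and 3.18 beyond 100 kb, and in HEK293T it was -0.337 and -0.349. Beyond 100 kb the IMR-90 value of 50.8% lay below the highest shuffle, 51.9%, so the shuffles showed no shared orientation at that distance. In HEK293T and IMR-90 the excess was 2.63 and 4.52 standard errors at 1 to 5 kb and 8.92 and 5.34 under 1 kb.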
